A study of Homo sapiens with 18 samples.

How the data were processed

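Total RNA from SK-N-BE(2) and CHLA-90 neuroblastoma cells was measured with biotin-labelled whole-transcript arrays, 3 per group, 72 hours after lentiviral transduction of 250000 cells per well with shNSC, shERK5-4 or shERK5-5. The deposited values are log2 signals, 1 per probe (transcript cluster) and array with 2 decimals, summarised and normalized by the authors. The log base is inferred from the range of the values. The summarisation method, the software and the genome build are not given in the sources used here. The medians of the 9 arrays of a line lie close together while those of the 2 lines differ, as if each line had been normalized apart. Changes within a line do not depend on that, while the comparison of the lines under shNSC does. No coordinates were used. No detection calls were used, so the background of each probe is unknown. Array signals have no depth, and the number of arrays limits the precision.

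All 21448 probes were tested. A table of the array's probes gave 17709 of them 1 gene symbol (17687 distinct symbols) and 3739 none, and unnamed probes were counted but not named. Symbols were checked by gene number against a current gene table, which changed 0 of them. A gene with several probes is represented by the probe with the highest mean.

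Groups were taken from the labels. One limma model (version 3.58.1 in R 4.3.3) with a mean for each of the 6 groups was fitted to the log2 values of all 18 arrays with lmFit and eBayes, with 12 residual and 9.588 prior degrees of freedom. Contrasts were each hairpin against shNSC in its line, the mean of the hairpins against shNSC, shERK5-4 against shERK5-5, the difference between lines in the mean hairpin effect, and the lines under shNSC. P-values were adjusted by Benjamini-Hochberg over all probes of a contrast, with a threshold of 0.05 and no minimum fold. A change shared by both hairpins is a probe past the threshold in both single hairpin contrasts with the same sign, and a change shared by both lines is past it in all 4. MAPK7 was also tested by exact two-sided permutation of the 6 hairpin arrays against the 3 shNSC arrays of a line. Errors of fold changes are standard errors of the model.

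The tests, 28 gene lists and the rule for naming genes were fixed before the data were examined. The lists come from general knowledge and have 690 entries, of which 601 had a probe. They were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a contrast. Camera with an estimated correlation, and fry, were run beside it. Genes named are MAPK7; in each line the 8 with the most positive and the 8 with the most negative mean change among those called alike with both hairpins; the same number for both lines together; up to 4 members of a described list with the smallest p in the mean contrast; 5 in each direction for the difference between lines and for the lines under shNSC, with MYCN; and 4 in each direction for the difference between hairpins in each line. Small RNA genes, unnamed open reading frames and non-coding genes known only by a locus name were passed over.

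Alternatives were median centring and quantile normalization of the arrays, leaving out probes with a mean below the 25 percentile, a replicate block, fits to the arrays of 1 line or of the compared groups, eBayes with trend and robust estimation, array weights, a minimum fold of 1.5, a threshold of 0.01, averaging the probes of a gene, each hairpin alone for the lists, and leaving out each array in turn. Leaving out 2 arrays together, and list tests between hairpins, were added after the data had been seen. The chance likeness of contrasts that share control arrays was simulated 50 times without any effect. The fit was tested on simulated data with the spread of these arrays and 200 changed probes. With a log2 change of 2 it recovered 100% of them in the single hairpin contrasts, with a change of 1 between 80.6% and 88.1%, and with a change of 0.5 between 2.99% and 10.4%, with 5 to 11 false calls. For both hairpins in both lines it recovered 58.2% at a change of 1 and 0% at 0.5, so small shared changes can be missed. The real single hairpin contrasts called 2721 to 5133 probes. With only 200 changed probes the adjustment is stricter than there, and every group was given the same spread. These percentages are therefore not the recovery in the real contrasts. Of the simulated lists, 2 of 2 shifted by 0.5 were called and 0 of 26 untouched ones. The simulated noise was independent between probes, so this does not test for false list calls that come from correlated genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.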

Results

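RNA was measured on 18 whole-transcript expression arrays from 2 human neuroblastoma lines, SK-N-BE(2) and CHLA-90. SK-N-BE(2) carries amplified MYCN, the oncogene whose amplification marks high-risk neuroblastoma, and CHLA-90 does not. Cells received lentivirus (pLKO vector, produced in HEK-293T cells) encoding the control hairpin shNSC or either of 2 short hairpin RNAs against ERK5, shERK5-4 and shERK5-5. ERK5 is the mitogen-activated protein kinase encoded by MAPK7. RNA was taken 72 hours after transduction, with 3 biological replicates in each of the 6 groups, so each line had 9 arrays. The arrays carried 21448 probes, each with a log2 signal. Array medians lay between 5.63 and 5.69 in SK-N-BE(2) and between 6.35 and 6.43 in CHLA-90. Arrays of the same group correlated across probes with r between 0.988 and 0.997, arrays of other groups of the same line with r between 0.971 and 0.989, and arrays of different lines with r between 0.913 and 0.933. The mean r within a group was 0.990 for SK-N-BE(2) shERK5-4 and for CHLA-90 shERK5-5, and 0.995 to 0.996 for every other group. Array signals have no read depth, and the number of arrays limits the precision. The series asks what silencing of ERK5 does to the transcriptome of neuroblastoma cells. Agreement of the 2 hairpins bears on whether a change follows the target or a single hairpin. Agreement of the 2 lines does not, since changes of a single hairpin also recurred in both lines. It bears on whether a change depends on the line.

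The target transcript was lower with both hairpins in both lines. MAPK7 (probe TC1700007170.hg.1) had a mean log2 signal of 6.78 ± 0.28 (SD, n = 3 in this and every group) in SK-N-BE(2) with shNSC, 6.09 ± 0.17 with shERK5-4 and 6.15 ± 0.13 with shERK5-5. In CHLA-90 the means were 8.42 ± 0.20, 7.35 ± 0.21 and 7.43 ± 0.35. Relative to shNSC, MAPK7 was at 61.8% with shERK5-4 and 64.3% with shERK5-5 in SK-N-BE(2), with log2 fold changes of -0.69 ± 0.20 (SE) and -0.64 ± 0.20 and adjusted p = 0.0103 and 0.0319 by limma. It was at 47.7% and 50.5% in CHLA-90, with log2 fold changes of -1.07 ± 0.20 and -0.99 ± 0.20 and adjusted p = 0.000329 and 0.00139. In each line all 6 hairpin arrays lay below all 3 shNSC arrays, and the exact two-sided permutation p was 0.0238, the smallest that the 84 assignments allow. The hairpins did not differ detectably in MAPK7, with log2 differences of shERK5-4 from shERK5-5 of -0.06 in SK-N-BE(2) (95% confidence interval -0.461 to 0.347) and -0.08 in CHLA-90 (-0.484 to 0.324). The mean hairpin effect in CHLA-90 minus that in SK-N-BE(2) was -0.36 (interval -0.856 to 0.133, adjusted p = 0.493). The SK-N-BE(2) calls rest on few arrays. The shERK5-4 call was lost without shNSC replicate 1 (log2 fold change -0.59, adjusted p = 0.061), and the shERK5-5 call without shNSC replicate 1 (adjusted p = 0.149), shNSC replicate 3 (0.11), shERK5-5 replicate 1 (0.0833) or shERK5-5 replicate 2 (0.123).

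**Figure D1:**
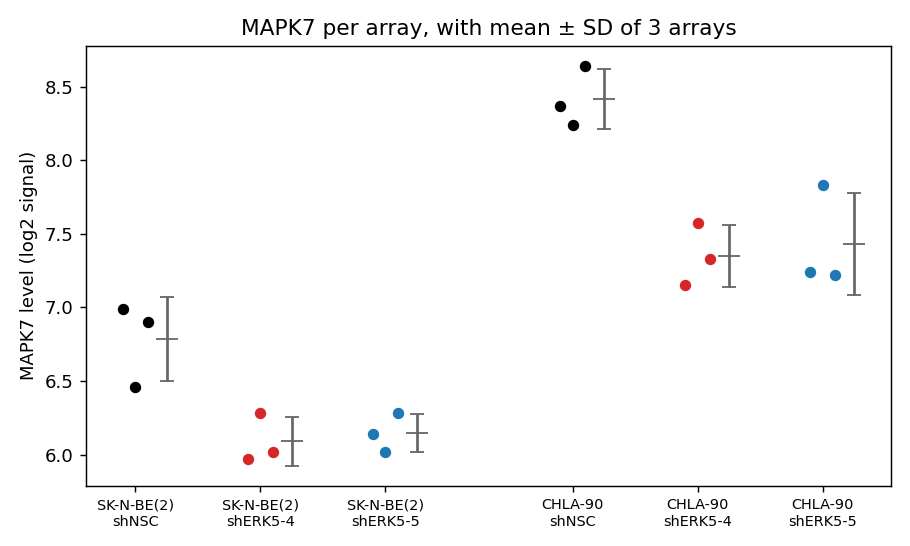
MAPK7 log2 signal (vertical axis, not starting at 0) of each of the 18 arrays by line and hairpin, with points for arrays and a cross line with bars for the mean ± SD of 3 arrays. In both lines the 6 points of shERK5-4 and shERK5-5 lie below the 3 points of shNSC.

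In SK-N-BE(2), the genes that rose most with both hairpins included DYNLRB1, a dynein light chain (log2 fold change 3.40 ± 0.18 with shERK5-4 and 4.69 ± 0.18 with shERK5-5), ABCA12, a lipid transporter (3.46 ± 0.21 and 3.21 ± 0.21), NECTIN1, an adhesion molecule (3.61 ± 0.25 and 2.99 ± 0.25), and TYRP1, an enzyme of melanin synthesis (2.56 ± 0.22 and 3.72 ± 0.22). HCN2, PLPPR2, MFAP4 and MAPRE3 rose as well, with mean changes of 2.95, 2.91, 2.66 and 2.65. Among genes called with both hairpins, those that fell most were B4GALT6, the lactosylceramide synthase (-5.14 ± 0.20 and -3.10 ± 0.20), CDK6, a kinase that drives G1 progression (-3.66 ± 0.18 and -2.53 ± 0.18), and GREM1, a secreted BMP antagonist (-4.50 ± 0.33 and -1.47 ± 0.33). GNG10, SYNPO2, GLUD1 and GPM6B fell too, with mean changes of -2.52, -2.49, -2.37 and -2.35, and so did the DNAJC25-GNG10 readthrough (-2.42), which shares sequence with GNG10. The largest adjusted p of these single hairpin changes was 0.00309, for GREM1 with shERK5-5. By limma, 5133 probes differed from shNSC with shERK5-4 (2616 higher, 2517 lower) and 2752 with shERK5-5 (1450 higher, 1302 lower). Both hairpins moved 1117 probes the same way (611 higher, 506 lower) and 416 in opposite directions. Independent calls would give 329.7 shared in direction. No such number was computed for opposite calls, so it is not shown whether these also exceed independent calls. Both contrasts use the same 3 shNSC arrays, which adds to their likeness.

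Among the gene lists, genes of the G1/S transition and DNA replication fell in SK-N-BE(2) with the mean of the hairpins. Of 37 measured members 23 were lower and 1 higher (25 and 1 adjusted over the list alone), with a median log2 change of -0.60 (camera adjusted p = 4.61e-14). The replication licensing factor CDC6 changed by -1.98, the ubiquitin ligase adaptor DTL by -1.28, E2F8 by -1.35 and the chromatin assembly factor CHAF1B by -1.39. Cholesterol synthesis genes fell, 12 of 20 lower and 0 higher (the same numbers adjusted over the list alone), with a median of -0.67 (adjusted p = 6.26e-09), HMGCS1 at -1.99, SQLE at -2.03, MSMO1 at -1.28 and the sterol regulator SREBF2 at -2.03. MYC targets and ribosome biogenesis genes fell, 8 of 25 lower and 0 higher (10 and 0 adjusted over the list alone), with a median of -0.40 (adjusted p = 2.39e-06), NOLC1 at -1.01 and NOP16 at -1.04. Homologous recombination and Fanconi repair genes fell, 6 of 16 lower and 0 higher (7 and 0 adjusted over the list alone), with a median of -0.37 (adjusted p = 0.00029), BRCA1 at -0.73 and EXO1 at -0.68. These 4 calls held with an estimated correlation. Of the 4, only the G1/S list was also called with each hairpin alone (with shERK5-5 adjusted p = 0.026; adjusted p = 0.327 with an estimated correlation), and with shERK5-5 alone cholesterol synthesis had a median of 0.01, MYC targets -0.20 and homologous recombination -0.07. The other 2 lists called did not hold with an estimated correlation. MAPK output and feedback genes were lower with the preset correlation, 10 of 21 lower and 2 higher (11 and 2 adjusted over the list alone), with a median of -0.44 (adjusted p = 0.00068; adjusted p = 0.108 with an estimated correlation). The immediate early genes IER3 and EGR1 fell (log2 change -1.76 and -1.79), ETV1 fell by 0.68 and ETV5 rose by 0.83. With shERK5-5 alone this list had a median of 0.27 and was not called. ATF4 and amino acid response genes were higher, 12 of 25 higher and 1 lower (14 and 1 adjusted over the list alone), with a median of 0.44 (adjusted p = 8.14e-05; adjusted p = 0.0853 with an estimated correlation). CHAC1, a glutathione-degrading enzyme induced by ATF4, rose by 1.87, VLDLR by 1.24 and PHGDH, which starts serine synthesis, by 0.93. The ATF4 list was called with shERK5-5 alone (median 0.65, adjusted p = 2.37e-10; adjusted p = 0.0239 with an estimated correlation) and not with shERK5-4 alone (median 0.23, adjusted p = 0.414).

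In CHLA-90, NECTIN1 (3.97 ± 0.25 with shERK5-4 and 3.69 ± 0.25 with shERK5-5) and DYNLRB1 (3.04 ± 0.18 and 3.28 ± 0.18) rose most with both hairpins. FBRSL1, MAPRE3, the autophagy protease ATG4D, PLPPR2, the mannose-6-phosphate receptor M6PR and HCN2 rose with mean changes between 2.08 (HCN2) and 2.74 (FBRSL1). Among genes called with both hairpins, the largest falls were in the antisense transcript ROR1-AS1 (-4.57 ± 0.23 and -2.69 ± 0.23), SYNPO2 (-5.16 ± 0.16 and -0.53 ± 0.16), ACTA2, the smooth muscle actin (-2.12 ± 0.20 and -3.49 ± 0.20), and TMEM97, a sterol-linked membrane protein (-4.63 ± 0.17 and -0.71 ± 0.17). HAND1, DLK1, CHGA and THBS1 fell with mean changes of -2.59, -2.55, -2.49 and -2.44. The largest adjusted p of the single hairpin changes of these genes was 0.028, for SYNPO2 with shERK5-5. By limma, 3918 probes differed from shNSC with shERK5-4 (2149 higher, 1769 lower) and 2721 with shERK5-5 (1255 higher, 1466 lower). Both hairpins moved 753 probes the same way (374 higher, 379 lower) and 300 in opposite directions. Independent calls would give 246.7 shared in direction, and no such number was computed for the opposite calls. Without shNSC replicate 3 the count for shERK5-5 was 1720 and the count for both hairpins 475.

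Gene lists in CHLA-90 gave 9 calls with the mean of the hairpins, all lower. G1/S and DNA replication genes fell, 16 of 37 lower and 1 higher (23 and 1 adjusted over the list alone), with a median of -0.47 (camera adjusted p = 4.31e-11), CDC6 at -1.46, DTL at -1.10 and the thymidylate synthase TYMS at -0.92. Cholesterol synthesis genes fell, 10 of 20 lower and 0 higher (14 and 0 adjusted over the list alone), with a median of -0.55 (adjusted p = 1.23e-10), SREBF2 at -1.82, MSMO1 at -1.15 and INSIG1 at -1.18. Extracellular matrix and TGF-beta genes fell, 7 of 27 lower and 0 higher (8 and 0 adjusted over the list alone), with a median of -0.12 (adjusted p = 0.000153), THBS1 at -2.44, TGFBI at -2.35, the proteoglycan BGN at -1.99 and the microfibril protein FBN1 at -1.61. These 3 calls held with an estimated correlation. The G1/S and matrix lists were also called with each hairpin alone (with shERK5-5 adjusted p = 2.93e-05 and 0.00771; adjusted p = 0.0992 for both with an estimated correlation), and cholesterol synthesis only with shERK5-4 (median -0.14 with shERK5-5). Adrenergic neuroblastoma identity genes, which mark the sympathetic cell state, were lower in 9 of 21 members and higher in 1 (12 and 1 adjusted over the list alone), with a median of -0.39 (adjusted p = 4.16e-09; adjusted p = 0.0502 with an estimated correlation). CHGA, DBH, HAND1 and ISL1 fell (log2 change -2.49, -2.88, -2.59 and -1.56), and with shERK5-5 alone the list median was 0.14. G2/M and mitosis genes were lower in 7 of 36 members and higher in 0 (8 and 0 adjusted over the list alone), with a median of -0.20 (adjusted p = 0.000578; adjusted p = 0.109 with an estimated correlation) and of 0.09 with shERK5-5 alone. CCNA2, FOXM1, AURKA and CDC25C fell (log2 change -1.52, -0.81, -0.87 and -1.20). Ribosomal proteins were lower in 3 of 21 members and higher in 0 (the same numbers adjusted over the list alone), with a median of -0.21 (adjusted p = 0.00131; adjusted p = 0.354 with an estimated correlation). With shERK5-4 alone their median was 0.02 and the list was not called (adjusted p = 0.504). ER chaperone and unfolded protein response genes were lower in 2 of 18 members and higher in 0 (4 and 0 adjusted over the list alone), with a median of -0.26 (adjusted p = 0.00767; adjusted p = 0.0877 with an estimated correlation), HYOU1 at -0.72, and were not called with shERK5-4 alone (median -0.06, adjusted p = 0.584). MYC targets and ribosome biogenesis genes had a median of -0.18 with 0 of 25 members past the threshold on either count (adjusted p = 0.0316; adjusted p = 0.15 with an estimated correlation). That call was lost without shNSC replicate 1 (adjusted p = 0.0818), shNSC replicate 3 (0.0549) or shERK5-5 replicate 1 (0.0695), and also with dim probes left out (0.0645) or without the 2 arrays least like their groups (0.0684), and with shERK5-4 alone the median was 0.01 (adjusted p = 0.89). Fibroblast markers had a median of 0.02 but a mean of -0.44, with 4 of 11 lower and 0 higher (5 and 1 adjusted over the list alone; adjusted p = 0.0331; adjusted p = 0.0936 with an estimated correlation), ACTA2 among them. The fibroblast call was lost without shNSC replicate 2 (0.0574) or shERK5-5 replicate 3 (0.078), with the replicate block (0.0655), and with shERK5-5 alone (median 0.24, adjusted p = 0.964).

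Of the 28 lists, 22 gave no call in SK-N-BE(2) (adjusted p from 0.0623 to 0.975) and 19 none in CHLA-90 (0.0536 to 0.981). Some of these were called with 1 hairpin alone at the preset correlation, or when 1 array was left out. In SK-N-BE(2) adrenergic identity was lower with shERK5-4 (median -0.42, camera adjusted p = 0.000106). With shERK5-5 ER chaperones were higher there (median 0.36, 0.026) and matrix genes lower (-0.04, 0.0478), and neither held with an estimated correlation. In CHLA-90 with shERK5-4, ATF4 genes (-0.23, 0.0246) and homologous recombination genes (-0.26, 0.0145) were lower. Further such calls are given below. In SK-N-BE(2) adrenergic identity was called without shERK5-4 replicate 3 (0.0223), shERK5-5 replicate 3 (0.0287) or shNSC replicate 2 (0.0271), matrix genes without shERK5-4 replicate 2 (0.0465) or shNSC replicate 1 (0.0339), lysosome and autophagy without shNSC replicate 3 (0.0386) and oxidative phosphorylation without shERK5-4 replicate 2 (0.0325). In CHLA-90 small RNA processing was called without shERK5-4 replicate 1 (0.0455) or 3 (0.0497), shERK5-5 replicate 1 (0.0233) or 2 (0.0389), or shNSC replicate 3 (0.0267). With all arrays and the mean of the hairpins, in neither line was a call made for ERK5 cascade and reported targets, CDK inhibitors and growth arrest, p53 targets, mesenchymal neuroblastoma identity, YAP/TEAD targets, neuronal differentiation, interferon-stimulated genes, NF-kB targets and cytokines, lysosome and autophagy, hypoxia and glycolysis, oxidative phosphorylation, apoptosis regulators, small RNA processing, Schwann cell markers, endothelial markers, or blood and immune cell markers. Within the ERK5 list, 3 of 18 members were higher and 2 lower in SK-N-BE(2). The lower were MYCN at -1.41 and MEF2A, a transcription factor that ERK5 phosphorylates, at -1.17, and MAP2K5 was among the higher at 0.86. In CHLA-90 3 were higher and 1 lower, with MAP3K2 at 0.68 and MEF2D at 0.645 among the higher. Each count was the same adjusted over the list alone. Median, mean and test differed in sign for NF-kB targets and cytokines and for apoptosis regulators in SK-N-BE(2). In CHLA-90 they differed for MAPK output and feedback, CDK inhibitors and growth arrest, p53 targets, neuronal differentiation, NF-kB targets and cytokines, oxidative phosphorylation, fibroblast markers, and blood and immune cell markers.

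Both hairpins in both lines moved 276 probes the same way, 147 higher and 129 lower, where independent calls of the lines would give 19.6. The 2 lines share no control arrays. Calls of each single hairpin also recurred in both lines, so 19.6 is a low reference for the agreement of the hairpins. DYNLRB1, NECTIN1, MAPRE3, PLPPR2, HCN2, ATG4D, FBRSL1 and PIP5K1C, a lipid kinase that makes PI(4,5)P2, rose most. NECTIN1 rose by 9.85-fold in SK-N-BE(2) and 14.2-fold in CHLA-90, and ATG4D by 5.71-fold and 5.38-fold. PIP5K1C was nearly uniform, at 2.19 ± 0.20 and 2.19 ± 0.20 in SK-N-BE(2) and 2.09 ± 0.20 and 1.95 ± 0.20 in CHLA-90. SYNPO2, GNG10, TGFBI, QDPR, GLUD1, DNAJC25-GNG10, SYNPO and FAF2 fell most. GLUD1, the mitochondrial glutamate dehydrogenase, changed by -2.06 ± 0.17 and -2.67 ± 0.17 in SK-N-BE(2) and -2.17 ± 0.17 and -2.16 ± 0.17 in CHLA-90, and GNG10 by -2.40 ± 0.20, -2.63 ± 0.20, -2.35 ± 0.20 and -2.24 ± 0.20. FAF2 changed by -3.72 and -2.92 with shERK5-4 but by -0.89 and -0.78 with shERK5-5. CDC6, of the G1/S list, changed by -2.39 and -1.57 in SK-N-BE(2) and -1.36 and -1.56 in CHLA-90. The mean changes of the lines correlated across probes with r = 0.498, and 1299 probes were called the same way in both against 74 opposite. Probes are not independent replicates.

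**Figure D2:**
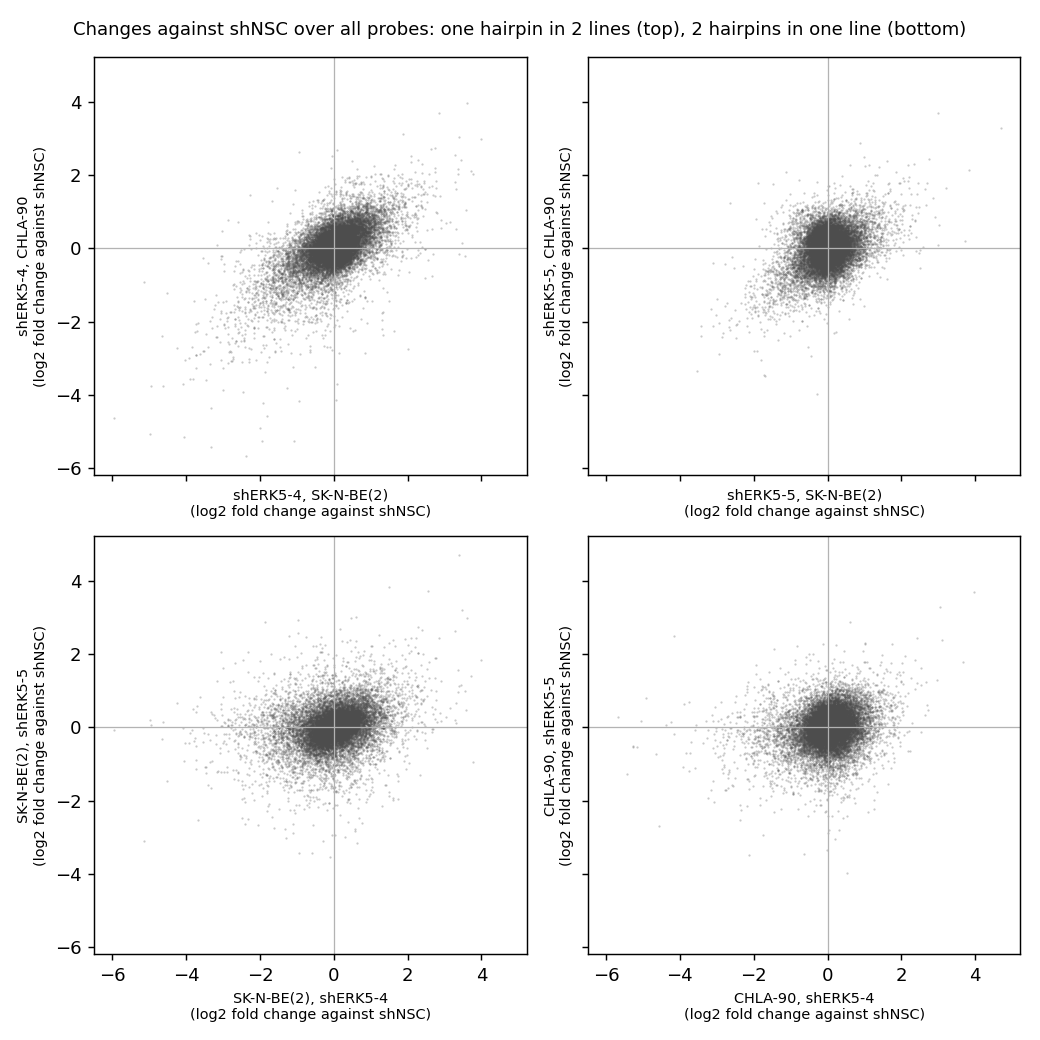
Log2 fold change against shNSC of every probe, with 1 point per probe and the same range on all axes. The upper panels set the lines against each other for shERK5-4 (r = 0.600) and shERK5-5 (r = 0.372), and the lower panels set the hairpins against each other in SK-N-BE(2) (r = 0.273) and CHLA-90 (r = 0.203).

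The hairpins differed from each other in both lines. RTN3, an endoplasmic reticulum shaping protein, fell with shERK5-4 (log2 change -4.96 in SK-N-BE(2) and -5.06 in CHLA-90) and stood at 0.19 and 0.18 with shERK5-5. TMEM97 stood at -5.96 and -4.63 with shERK5-4 and -0.06 and -0.71 with shERK5-5, and SREBF2 at -3.90 and -3.58 against -0.16 and -0.07. STARD7, a phosphatidylcholine transfer protein, did the reverse, at -0.10 and -0.01 with shERK5-4 and -3.55 and -3.35 with shERK5-5. Other genes past the threshold for the difference, shERK5-4 minus shERK5-5, were PTBP2 (4.72), TGFBR1 (3.79), CHML (3.67), SHD (3.63), HGF (-5.11) and PPIL1 (-4.89) in SK-N-BE(2). In CHLA-90 they were MAGEC1 (4.52), VSNL1 (3.47), ZDHHC20 (3.39), DLX5 (-6.63), GPR50 (-5.94) and PRR16 (-5.70). MYCN changed by -2.02 ± 0.17 with shERK5-4 and -0.80 ± 0.17 with shERK5-5 in SK-N-BE(2), and by -1.89 ± 0.17 and 0.97 ± 0.17 in CHLA-90. Cholesterol synthesis genes were lower with shERK5-4 than with shERK5-5, 15 of 20 in SK-N-BE(2) (median -1.14, camera adjusted p = 3.33e-11) and 13 in CHLA-90 (median -0.81, adjusted p = 5.74e-07), with 15 and 14 adjusted over the list alone, and none higher except 1 in CHLA-90 adjusted over the list alone. G2/M and mitosis genes were lower as well, 29 of 36 (median -0.91, adjusted p = 9.88e-17) and 18 (median -0.48, adjusted p = 2.59e-06), with 33 and 23 adjusted over the list alone, and 2 higher in CHLA-90 (3 adjusted over the list alone). Both lists held in both lines with an estimated correlation. In all, 10 lists were called lower and 0 higher with shERK5-4 than with shERK5-5 in SK-N-BE(2), of which 6 held. In CHLA-90 7 were called lower and 5 higher, of which 4 held. In SK-N-BE(2) the G2/M list was called lower with shERK5-4 (median -0.59, adjusted p = 1.1e-09, held with an estimated correlation) and higher with shERK5-5 (median 0.41, adjusted p = 2.09e-05; adjusted p = 0.124 with an estimated correlation). CCNA2 and FOXM1 stood at -2.64 and -2.66 with shERK5-4 in SK-N-BE(2) and at -2.54 and -1.93 in CHLA-90. With shERK5-5 they stood at -0.16 and 0.79, and at -0.50 and 0.31. Adrenergic identity genes were lower with shERK5-4 than with shERK5-5 in CHLA-90 (median -0.92, 12 of 21, 13 adjusted over the list alone, adjusted p = 1.03e-10, held with an estimated correlation). The list was also lower in SK-N-BE(2) (median -0.63, 11 members lower and 0 higher, 12 and 1 adjusted over the list alone, adjusted p = 4.37e-06; adjusted p = 0.0874 with an estimated correlation). By limma, 5246 probes differed between the hairpins in SK-N-BE(2) (2538 higher and 2708 lower with shERK5-4) and 5825 in CHLA-90 (3174 and 2651). The same hairpin moved 2237 probes the same way in both lines for shERK5-4 (101 opposite) and 982 for shERK5-5 (72 opposite). Across probes, changes of the same hairpin in the 2 lines correlated with r = 0.600 for shERK5-4 and 0.372 for shERK5-5, and changes of different hairpins in different lines with r = 0.103 and 0.0971. Hairpins of the same line gave r = 0.273 in SK-N-BE(2) and 0.203 in CHLA-90. In simulated data without any effect the 3 shared shNSC arrays alone give r = 0.5. Those contrasts hold noise only, while effects add to the variance of the real ones, so the observed r cannot be read against 0.5. The observed covariances of 0.0826 and 0.0504 were above the simulated 0.0224 and 0.0223.

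**Figure D3:**
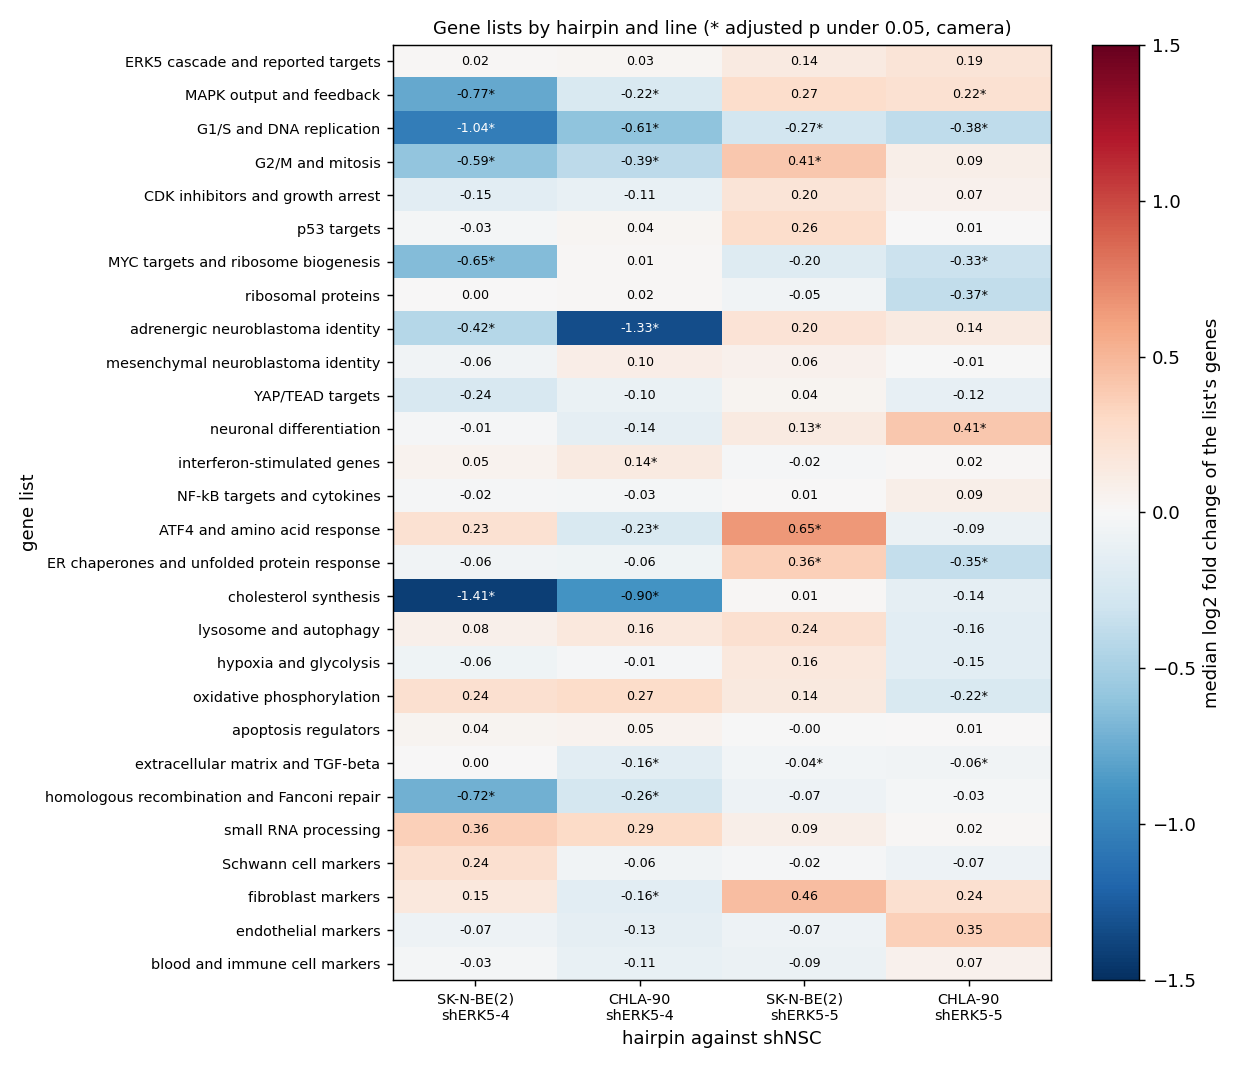
Median log2 fold change against shNSC (colour and number) of the measured genes of each of 28 gene lists (vertical axis), by line and hairpin (horizontal axis), with asterisks for a camera adjusted p under 0.05 at the preset correlation. Cholesterol synthesis stands at -1.41 and -0.90 with shERK5-4 and at 0.01 and -0.14 with shERK5-5.

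The lines differed in part of their response, taken as the mean over the 2 hairpins, which need not act alike. B4GALT6 changed by -4.12 in SK-N-BE(2) and -0.66 in CHLA-90, a difference (CHLA-90 minus SK-N-BE(2)) of 3.46 ± 0.24. SEMA3A, a secreted axon guidance cue, fell by 1.31 in SK-N-BE(2) and rose by 1.49 in CHLA-90, and IER3 fell by 1.76 and rose by 0.68. CREB5 fell by 1.44 and rose by 0.95, and EGR1 stood at -1.79 and 0.39. In the other direction were TYRP1 (difference -3.21 ± 0.27), GFRA2, a neurturin co-receptor (-3.08 ± 0.28), PREX1 (-2.60 ± 0.29), ROR1-AS1 (-2.46 ± 0.29) and ABCA12 (-2.45 ± 0.26). By limma, 942 probes differed between the lines in the mean hairpin effect, 470 with the higher value in CHLA-90 and 472 with the lower. That count was 618 without SK-N-BE(2) shNSC replicate 1, 562 without SK-N-BE(2) shNSC replicate 2 and 512 without CHLA-90 shNSC replicate 3. Of 28 lists, 11 were called for the difference and none held with an estimated correlation. ATF4 and amino acid response genes were relatively lower in CHLA-90 (median difference -0.51, 8 of 25 lower and 0 higher, 13 and 0 adjusted over the list alone, camera adjusted p = 3.5e-08; adjusted p = 0.0513 with an estimated correlation). MAPK output and feedback genes were relatively higher (median 0.21, 4 of 21 higher and 0 lower, 6 and 0 adjusted over the list alone, adjusted p = 0.00227; adjusted p = 0.146 with an estimated correlation). In CHLA-90 that list was called in opposite directions by the hairpins, lower with shERK5-4 (median -0.22, adjusted p = 0.025; adjusted p = 0.264 with an estimated correlation) and higher with shERK5-5 (median 0.22, adjusted p = 0.0031; adjusted p = 0.199 with an estimated correlation). The hairpins differed in it in SK-N-BE(2) (adjusted p = 5.52e-09, held with an estimated correlation) and CHLA-90 (adjusted p = 0.000269; adjusted p = 0.0862 with an estimated correlation), so the difference between lines is one of means over unlike hairpins. Adrenergic identity genes were relatively lower (median -0.50, 5 of 21 lower and 1 higher, 9 and 2 adjusted over the list alone, adjusted p = 0.000786; adjusted p = 0.209 with an estimated correlation). MYC targets, called in both lines, differed as well (median 0.23, 1 of 25 higher and 0 lower, 3 and 0 adjusted over the list alone, adjusted p = 0.006; adjusted p = 0.131 with an estimated correlation).

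Under the control hairpin the lines differed in many transcripts. MYCN had a log2 signal of 17.13 ± 0.08 (SD, n = 3) in SK-N-BE(2) and 8.80 ± 0.18 in CHLA-90, a difference of -8.33 ± 0.17 (limma adjusted p = 2.85e-20). Highest in CHLA-90 relative to SK-N-BE(2) were TMEM176A (11.96 ± 0.20), the cancer-testis genes SSX1 (11.66 ± 0.21) and SSX2B (10.53 ± 0.20), the protocadherin FAT1 (9.42 ± 0.21) and CAMK2N1 (9.22 ± 0.24). Lowest were ENPP2, the secreted lysophospholipase autotaxin (-11.04 ± 0.19), S100A11 (-10.76 ± 0.17), the prostaglandin receptor PTGER2 (-9.14 ± 0.22), CORIN (-9.10 ± 0.20) and IGFBP3 (-8.71 ± 0.22). MAPK7 was higher in CHLA-90 by 1.63 ± 0.20, but by 0.915 ± 0.20 with array medians set equal and by 0.952 ± 0.19 after quantile normalization (adjusted p = 2.21e-07, 0.00047 and 0.000284), so its size depends on the scaling. As deposited, 12861 probes differed, 10371 higher and 2490 lower in CHLA-90, with a median log2 difference over all probes of 0.45. With array medians set equal, 4110 were higher and 7960 lower (median -0.26), and after quantile normalization over the 18 arrays 5067 were higher and 5277 lower (median -0.03). The balance of directions therefore depends on the scaling between lines. The 11 genes named first here kept their direction under every scaling, but shifts of this size could not have turned differences as large as theirs.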

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

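The tests of the difference between lines were chosen before the data were examined, and of the tests in this part only the removal of 2 arrays together was chosen only after the result was seen. The results below stand out because the mean hairpin effect differed between CHLA-90 and SK-N-BE(2) by a test of the difference itself. Groups of 3 arrays are too small to test single arrays against their group.

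In all, 942 probes passed the test. Among the genes named here, 43 passed it. The mean hairpin effect in CHLA-90 minus that in SK-N-BE(2) was positive, as a log2 difference, for B4GALT6 (3.46), SEMA3A (2.80), IER3 (2.44), CREB5 (2.39), EGR1 (2.18), GREM1 (2.14) and CDK6 (1.82). It was also positive for PTGER2 (1.19), SQLE (1.14), GPM6B (1.07), MEF2A (0.99), MYCN (0.95), HMGCS1 (0.93) and NOLC1 (0.80). The difference was negative by over 2 for TYRP1 (-3.21), GFRA2 (-3.08), PREX1 (-2.60), ROR1-AS1 (-2.46), ABCA12 (-2.45), DBH (-2.34), CHAC1 (-2.33), HAND1 (-2.33), MFAP4 (-2.31) and ACTA2 (-2.04). It was negative by less for PRR16 (-1.98), DCX (-1.95), BGN (-1.94), VLDLR (-1.64), MAGEC1 (-1.55), GPR50 (-1.45), CHGA (-1.39), SHD (-1.26), THBS1 (-1.21), DLK1 (-1.16), PHGDH (-1.16), CAMK2N1 (-1.06), VSNL1 (-1.06), ENPP2 (-1.02), TMEM176A (-1.01), HYOU1 (-0.93), FBN1 (-0.92), MDM2 (-0.91) and DYNLRB1 (-0.89). PTGER2, CAMK2N1, ENPP2 and TMEM176A were named for their large difference between the lines under shNSC. A low signal in 1 line may limit the change that can be seen there, which was not tested. Several of the 43 are mean effects of opposite sign. IER3 fell by 1.76 in SK-N-BE(2) and rose in CHLA-90 by 0.68, SEMA3A fell by 1.31 and rose by 1.49, and GFRA2 rose by 0.84 and fell by 2.23.

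Of the gene lists, 11 passed camera at the preset correlation. The median log2 difference was positive for MAPK output and feedback (0.21), G1/S and DNA replication (0.18), MYC targets and ribosome biogenesis (0.23) and homologous recombination and Fanconi repair (0.28). The negative medians were those of p53 targets (-0.16), ribosomal proteins (-0.21), adrenergic neuroblastoma identity (-0.50), ATF4 and amino acid response (-0.51), ER chaperones and unfolded protein response (-0.30), lysosome and autophagy (-0.36) and fibroblast markers (-0.24). None of the 11 passed with an estimated correlation, where the adjusted p ran from 0.0513 to 0.549. Leaving out dim probes ended 3 of them, ribosomal proteins (adjusted p = 0.0519), lysosome and autophagy (0.0537) and homologous recombination (0.0519). Removal of the 2 arrays least like their groups ended those of ribosomal proteins (0.136) and homologous recombination (0.0638). Leaving out 1 array ended 4 of the 11. For G1/S the adjusted p was 0.0529 without CHLA-90 shERK5-5 replicate 3 and 0.0534 without CHLA-90 shNSC replicate 2. For homologous recombination it was 0.0617 without CHLA-90 shERK5-4 replicate 2, 0.0862 without CHLA-90 shNSC replicate 3 and 0.0888 without SK-N-BE(2) shNSC replicate 1. For lysosome and autophagy it was 0.0733 without CHLA-90 shERK5-5 replicate 2, 0.111 without CHLA-90 shNSC replicate 3 and 0.139 without SK-N-BE(2) shNSC replicate 1. For ribosomal proteins it was 0.084 without CHLA-90 shERK5-5 replicate 1, 0.103 without CHLA-90 shNSC replicate 1, 0.0843 without CHLA-90 shNSC replicate 3 and 0.0611 without SK-N-BE(2) shNSC replicate 3. Oxidative phosphorylation, not among the 11, was called without CHLA-90 shNSC replicate 2 (0.0226), SK-N-BE(2) shERK5-4 replicate 2 (0.014) or SK-N-BE(2) shNSC replicate 2 (0.0386).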

How the results depend on the processing

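The removal of 2 arrays together and the list tests between hairpins were chosen only after the result was seen. Every total count of probes kept within 1.5 times its reported value under median centring, quantile normalization, removal of dim probes, the replicate block, trend and robust estimation, array weights, a minimum fold of 1.5, averaged probes, and removal of the 2 arrays least like their groups. The counts by direction did so too, except for the lines under shNSC with median centring (10371 higher and 2490 lower became 4110 and 7960) and quantile normalization (5067 and 5277), and for shERK5-4 in CHLA-90 with array weights (2149 higher became 3284); the cause was not tested. At a threshold of 0.01 the counts fell, since fewer probes pass, to 1733 for shERK5-5 in SK-N-BE(2), 2481 and 1335 for shERK5-4 and shERK5-5 in CHLA-90, 2369 and 1471 for the mean of the hairpins in SK-N-BE(2) and CHLA-90, 3715 for the difference between hairpins in CHLA-90, 371 for the difference between lines, 658 and 343 for both hairpins in SK-N-BE(2) and CHLA-90, and 131 for both hairpins in both lines. MAPK7 in SK-N-BE(2) stayed at -0.69 and -0.64 but missed 0.01. With only the compared arrays fitted, shERK5-5 in CHLA-90 gave 1612 against 2721 and shERK5-4 in SK-N-BE(2) 4213 against 5133. By contrast, shERK5-4 in CHLA-90 rose to 4960 and shERK5-5 in SK-N-BE(2) to 3187. Of these contrasts, those that fell hold the hairpin groups with the lower within-group correlation. The main fit uses 1 spread per probe for all groups, so its counts are not directly comparable between hairpins. The cause of the changes was not tested. Fry, which asks another question than camera, called 17 lists in SK-N-BE(2). Camera with an estimated correlation called 3 in CHLA-90 and 0 for the difference between lines. With shERK5-5 alone 3 called lists turned direction in both camera and median, to 0.27 for MAPK output and feedback in SK-N-BE(2), 0.09 for G2/M and mitosis in CHLA-90 and 0.14 for adrenergic identity in CHLA-90; the cause was not tested. In other called lists only the median changed sign, to 0.01 for cholesterol synthesis in SK-N-BE(2) with shERK5-5 alone, and in CHLA-90 with shERK5-4 alone to 0.02 for ribosomal proteins, 0.01 for MYC targets and -0.16 for fibroblast markers. Medians of lists not called changed sign too, among them G2/M (0.41, called) and adrenergic identity (0.20) in SK-N-BE(2) with shERK5-5 alone. Leaving out 1 array gave 475 to 726 for both hairpins in CHLA-90 and 1720 to 2822 for shERK5-5 in CHLA-90, with both lowest counts without shNSC replicate 3. It gave 512 to 1098 for the difference between lines, lowest without CHLA-90 shNSC replicate 3, with 618 and 562 without SK-N-BE(2) shNSC replicates 1 and 2. MAPK7 in SK-N-BE(2) ranged from -0.85 to -0.59 with shERK5-4 and from -0.80 to -0.53 with shERK5-5; the cause was not tested. Arrays with the same replicate number in a line had a median residual correlation of 0.0374 in SK-N-BE(2) and 0.0821 in CHLA-90, and the block gave 283 probes for both hairpins in both lines. Under the block, 7 lists were called in SK-N-BE(2), with adrenergic identity added (adjusted p = 0.039), and 8 in CHLA-90, without fibroblast markers (adjusted p = 0.0655), and no other list call changed. Quantile normalization added a call of small RNA processing as higher in CHLA-90 (0.0361). Removal of the 2 arrays added calls of oxidative phosphorylation in SK-N-BE(2) (0.0204), ATF4 and amino acid response (0.0457) and small RNA processing (0.0198) in CHLA-90, and oxidative phosphorylation for the difference between lines (0.00917). Low signals limit what can be seen, since background is unknown.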

Other observations

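All counts over other splits of the arrays, and the comparison of shared calls with independent ones, were tests chosen only after the result was seen, as were a second matching of random lists to the nearest signal levels and the list tests between hairpins; for the difference between hairpins, opposite calls within each line had been seen before the test across lines.

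Beyond the lists called in the report, several neuronal genes moved, some of them differently with the 2 hairpins. The RNA-binding protein gene ELAVL3 rose with both hairpins in SK-N-BE(2) (0.59 with shERK5-4 and 2.19 with shERK5-5) and CHLA-90 (1.75 and 2.28), while the neurofilament gene NEFL stood at -1.34 and -1.71 in SK-N-BE(2) and at -0.64 (adjusted p = 0.122) and -3.45 in CHLA-90. SYT1, which encodes a calcium sensor of synaptic vesicles, rose with shERK5-5 by 0.78 and 0.88 and fell with shERK5-4 (-1.32 and -2.24). The microtubule-associated gene DCX rose with shERK5-5 by 2.39 and 1.12, and stood at 0.45 in SK-N-BE(2) and -2.18 in CHLA-90 with shERK5-4. With shERK5-5 the neuronal differentiation list was higher in SK-N-BE(2) (median 0.13, 7 of 23 higher and 2 lower, 10 and 4 adjusted over the list alone, camera adjusted p = 0.026; adjusted p = 0.327 with an estimated correlation). It was also higher in CHLA-90 (median 0.41, 9 higher and 1 lower, 11 and 2 adjusted over the list alone, adjusted p = 0.00971; adjusted p = 0.294 with an estimated correlation). Tested between hairpins, the list was lower with shERK5-4 than with shERK5-5 in SK-N-BE(2) (13 lower and 4 higher, 13 and 5 adjusted over the list alone, adjusted p = 0.00485; adjusted p = 0.184 with an estimated correlation) and CHLA-90 (9 and 5, 11 and 6 alone, 0.0297; 0.271).

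Single genes of lists that gave no call with the mean of the hairpins also moved. MDM2, which encodes the ubiquitin ligase that restrains p53, rose with both hairpins in SK-N-BE(2) (2.28 and 2.04) and CHLA-90 (1.49 and 1.01), while the p53 target list was not called in either line. The anti-apoptotic gene BCL2 fell in all 4 hairpin contrasts, with log2 changes of -2.64 and -1.17 in SK-N-BE(2) and -2.54 and -0.96 in CHLA-90. BIRC5, which encodes survivin, fell with shERK5-4 (-2.68 and -2.57), rose with shERK5-5 in SK-N-BE(2) by 1.75 and stood at 0.39 in CHLA-90. Interferon-stimulated genes were higher with shERK5-4 in CHLA-90 (median 0.14, 9 of 33 higher and 1 lower, the same numbers adjusted over the list alone, camera adjusted p = 0.0424; adjusted p = 0.0654 with an estimated correlation), and SAMD9L rose with shERK5-4 in both lines (2.25 and 1.83) and stood at -0.10 and -0.22 with shERK5-5.

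Responses that differ between the hairpins recur in both lines. A difference in the strength of silencing is argued against, since 92 probes passed the threshold in all 4 hairpin contrasts with opposite signs for the hairpins and the same orientation in both lines, 51 of them higher with shERK5-4, where strength alone would place effects along 1 direction and at most 20 were set as the bound. Silencing of other transcripts through the seed of each hairpin may account for part of the pattern and stays open. Probes called alike in both lines with 1 hairpin and not with the other were lower in 52.1% of cases, but the hairpins differed. With shERK5-4 573 of 1191 such probes were lower and 618 higher, and with shERK5-5 199 of 291 were lower and 92 higher. The pooled share lay below the bound set in advance for seed silencing, and the share with shERK5-5 above it. No share was set as excluding it, since neither hairpin sequences nor 3' UTRs were analysed here.

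In CHLA-90 with shERK5-5, camera called 6 lists lower and 2 higher, and none of these held with an estimated correlation. Among those lower were ribosomal proteins (5 of 21 lower and 0 higher, 9 and 0 adjusted over the list alone, camera adjusted p = 2.93e-05; adjusted p = 0.261 with an estimated correlation), ER chaperones (5 of 18 and 0, 7 and 0 alone, 0.000225; 0.0671) and oxidative phosphorylation (2 of 39 and 0, 2 and 0 alone, 0.00971; 0.451). Only these 3 were examined for compression of the signal. The arrays of that group had a narrower spread of signal over probes (SD 3.29 against 3.35 with shNSC), and a compressed distribution would lower bright genes in general. Among 10000 random lists matched on level, the ribosomal protein median of -0.37 lay at percentile 0.18 (0.02 with the nearest levels), below the bound of 0.5. The list thus fell further than random genes of like level, although 18 of its 21 genes are in the brightest of 20 level bins. Random lists lack the correlation between genes of the list, so their spread may be too narrow. The percentile therefore does not decide about compression. For ER chaperones (0.88, but 0.35 with the nearest levels) and oxidative phosphorylation (3.31 and 2.3) compression cannot be told apart from a change of the genes, because the percentiles of the matching set in advance fall between its bounds (below 0.5 and from 5 up) and the 2 matchings put ER chaperones on different sides of 0.5. No biological explanation was tested.

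Probes changed alike by both hairpins in both lines could reflect chance deviation of the shNSC arrays that the hairpins of a line share. The overlap was 14.1 times that of independent calls, and the lines have separate shNSC arrays. However, calls of each single hairpin recurred in both lines. With shERK5-4 2237 probes were called alike against 469.7 for independent calls, and with shERK5-5 982 against 173.8. Such recurrence also raises the overlap, so the ratio does not decide about chance deviation of the shNSC arrays. An effect of the control hairpin itself stays open, since no untransduced arrays were analysed here, and the median ratio of the CHLA-90 change to the SK-N-BE(2) change of 0.869 does not separate it from silencing of ERK5. Of the probes called alike by both hairpins in each line, 3 went in opposite directions in the lines.

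Other splits of the arrays were fitted to the arrays compared only. For the mean of the hairpins the 6 hairpin arrays of a line were there fitted as 1 group, so differences between hairpins added to the spread. The real counts of that fit were below the 3649 and 2544 of the main fit. For the comparisons of 3 against 3 arrays, 1 of 10 splits gave as many calls, the real one, so the splits are too few for a share under 0.05. The real counts were 4213 and 3187 for shERK5-4 and shERK5-5 in SK-N-BE(2), 4960 and 1612 in CHLA-90, 4456 and 4879 for the difference between hairpins in SK-N-BE(2) and CHLA-90, and 13589 for the lines under shNSC, and the highest other split of each gave 0. For the mean of the hairpins, 3 of 84 splits gave as many calls in SK-N-BE(2) (760 in the real split) and 3 of 84 in CHLA-90 (407 in the real split). The highest others were 4026 and 3500, with the shERK5-4 arrays set apart, and setting the shERK5-5 arrays apart gave 1216 and 1863, so each hairpin group stands further from the remaining arrays of its line than the shNSC group does. The number of lists called was matched by 39 of 84 splits in SK-N-BE(2) (6 lists, highest other 11) and 15 of 84 in CHLA-90 (8 lists, highest other 11), so chance is not excluded for those numbers. For calls by both hairpins, 2 of 100 splits were as large in SK-N-BE(2) (989, highest other 2388) and 1 of 100 in CHLA-90 (678, highest other 0), and in both lines together 1 of 100 (276, highest other 4). The median of the other splits was 0 calls in each. Splits that mix the groups put differences between hairpins into the spread, so few calls were likely in them. The shares therefore show that the arrays differ by group, but they do not exclude chance for the number of shared calls. For the difference between lines 2 of 100 splits gave as many probes (942, highest other 3371). These splits also break up the hairpin effects within each line, so they do not test the difference between lines alone. Chance is therefore not excluded by this count, and a split with several times the real number again shows structure among the arrays. As many lists were called by 4 of 100 (11, highest other 13), a share under 0.05, but other splits called a median of 4 lists and none of the 11 held with an estimated correlation, so this count does not show that any one list differs between the lines.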
